A study of Homo sapiens with 24 samples.

How the data were processed

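Gene expression was measured on 24 Agilent 2-colour arrays in T47D cells, a human breast cancer line that carries the progesterone receptor. Per the labels, there were 12 conditions, made of 6 treatments and the sample letters A and B. The treatments were R5020, MAA, U0126, R5020 + MAA, R5020 + U0126 and R5020 + MAA + U0126. R5020 is a synthetic progestin and U0126 is an inhibitor of the kinase MEK. Each condition was hybridised on 2 arrays against a pooled control with the dyes reversed. The series title names isoforms A and B of the progesterone receptor, but no label spells out what the letters A and B stand for. The labels also leave out what MAA abbreviates, what the pooled control was made of, and the doses and times. The letters and MAA are therefore used as printed.

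Per the labels, 500 ng of total RNA was amplified, and 750 ng of cRNA of each dye was hybridised for 17 h. The authors extracted each scan with Agilent Feature Extraction, version A.7.5.1 per the file headers and 7.5 per the labels. The deposited scanner files hold spot and background intensity per channel in scanner units, where Cy3 is green and Cy5 is red. They also hold, per the file headers, a log10 ratio of Cy5 over Cy3 after spatial detrending and LOWESS dye normalization. Per the labels, the values were loaded into Rosetta Resolver 6.0. The deposited value matrix gives log10 ratios, and on 100% of spots they equalled the Feature Extraction ratios within 0.0001 once turned to treated over pooled control. The median of every column of that matrix was 0, and its genes were not centred.

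The scanner intensities were read in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Background was corrected with normexp (offset 50) on mean signal and median local background, and each array was normalized with loess. Control spots had weight 0 in the loess and were then left out, as were spots marked as outliers by the scanner software. Saturated spots were kept. Ratios were turned to log2 of treated over pooled control, spots of the same probe were averaged, and the 2 arrays of a condition were averaged and counted as 1 replicate. A condition with an outlier spot on either array was missing for that probe, because an array of a single orientation carries the dye effect. This touched 4174 of the features tested, and left a single sample in a group that the comparison needs for 68 of the features called for R5020 in A, 41 in B, 439 for R5020 alone, and 11 and 129 for the departures with MAA and U0126. A probe was kept when it was well above background in the treated channel on both arrays of at least 1 condition, or in the control channel on at least 12 of 24 arrays. That kept 39845 of 41000 probes.

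Probes were named through RefSeq accessions (16223 probes), current symbols (1588) or synonyms (651), and 22538 probes matched no name there. For a gene with several probes the brightest one was tested, and testing every probe was an alternative. This left 35654 features, of which 14827 had a gene symbol and 20827 did not. No genome was supplied, so no coordinates are given.

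Models were fitted with limma (lmFit and eBayes) to the 12 averages, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p. The first model had an offset for each letter and additive terms for R5020, MAA and U0126 within each letter (4 residual degrees of freedom, 3.99 prior). In that model the letter offset cancels the pooled control. The second model had a mean for each of the 6 treatments and a letter term (5 residual degrees of freedom, 5.13 prior). It gave R5020 alone against the pooled control, the difference between B and A over all treatments, and departures from additivity. A departure is the combined treatment minus the sum of the single treatments. Where a ratio is tested against 0, the test leaves out the spread of the control itself. Nothing in the labels says that the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. In the second model the treatment means pair the A and B samples by treatment. In the first, departures shared by both letters stay in the residual of the difference between letters, so that difference was also fitted with a mean for each treatment (2 residual degrees of freedom, 5.15 prior), an alternative chosen after the values were seen.

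The comparisons, the rule for named genes, 20 gene lists and the alternatives were fixed before the data were examined. The rule names PGR first. It then takes the 10 highest and 10 lowest log2 changes that passed for R5020 in each letter, MAA and U0126, and 5 of each for other comparisons. Such genes had a symbol, were well above background in both channels on at least 12 of 24 arrays, and were saturated on none. Some genes that meet the rule are left out of the text. Where nothing passed, the 3 smallest unadjusted p in each direction were taken and are named as not passing. Genes that passed were also checked in the treated channel of all arrays with and all arrays without the compound, over both letters. Some were not well above background on any array of 1 of these groups. They numbered 1 for R5020 in A, 1 in B, 4 for MAA and 4 for R5020 alone. Their bounds were not computed, so no fold is given for them.

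The 20 lists, each taken from general knowledge, covered progestin targets, output of the MEK/ERK pathway, immediate early genes, genes raised and genes lowered by inhibitors of histone deacetylases, the cell cycle, fatty acid synthesis, cholesterol synthesis, metallothioneins, interferon response, endoplasmic reticulum (ER) stress and amino acid response, estrogen targets, hypoxia and glycolysis, adhesion and cytoskeleton, steroid receptors, housekeeping genes, and markers of luminal epithelium, basal and mesenchymal cells, leukocytes and fibroblasts. Lists share genes. MT2A is in the progestin and metallothionein lists, RRM2 and TYMS are in the cell cycle list and that of genes lowered by deacetylase inhibitors, and MT1E and MT1X are in the list of genes raised by them and among the metallothioneins. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Both p-values were adjusted over the 20 lists of a comparison.

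Alternatives were Feature Extraction's own ratios, the deposited value table, median centring, Aquantile between arrays, no background subtraction, no filter, a stricter filter that kept 33424 probes, every probe, no letter term, a threshold of 0.01, all 24 arrays with a dye term and the pair as a random block, the same fit with extraction day as a block, and leaving out each condition and each array in turn. The headers gave 5 days on which scans were extracted, and each day held more than 1 condition. Some days held arrays of A only or of B only, so day and letter were in large part confounded. Within a day, pairs of arrays of the same dye that differed in 1 treatment or in the letter were also compared. These arrays had also entered the calls, which favours the same sign.

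The number of arrays limits the precision, and the signal over background may do so. Spots well above background ranged from 89.9% to 97.9% per channel and array. Recovery was tested on simulated data for 31480 features measured in all conditions, with 50 features changed at each size and seed 7. Noise was drawn as independent normal values with each feature's residual standard deviation from the second model. It lacks correlation between genes and, for comparisons of the first model, departures from additivity, so recovery in the data may be lower. At a log2 change of 0.25, recovery was 46% for R5020 in A, 44% in B and 20% for the difference between letters. It was 82% for MAA and 16% for its difference between letters, and 80% for U0126 and 18% for its difference. For R5020 alone it was 64%, for the departure with MAA 42%, for the departure with U0126 22%, and for B against A over all treatments 90%. At 0.5 the same comparisons, in that order, gave 90%, 94%, 74%, 98%, 80%, 100%, 84%, 98%, 76%, 88% and 100%. At log2 changes of 1 and 2 recovery was at least 96% in every comparison. Between 3 and 15 of the 31280 unchanged features were called in each.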

Results

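The data were 24 2-colour arrays of T47D breast cancer cells, 2 for each of 12 conditions, with 41675 spots for transcripts on each array. The median spot intensity ranged from 152.9 to 296.2 in Cy3 and from 206.6 to 492.0 in Cy5. In each letter, 4 samples had R5020 and 2 did not, and over both letters 6 samples had MAA and 6 had U0126. The 2 samples without R5020 in each letter were MAA alone and U0126 alone. The R5020 effects in A and B are therefore measured against treated samples and rest on additivity. Changes are log2 values with their standard error (SE) after ±, unless SD is written. For each comparison the adjusted p is limma's, from dye-swap averages in which a pair of arrays is 1 replicate. Per condition, genes with a log2 ratio of at least 1 in size on both arrays were counted with no test, and brackets give the counts with Feature Extraction's ratios, which were larger throughout. R5020 gave 141 higher and 32 lower in A (238 and 58), and 178 higher and 44 lower in B (308 and 76). MAA gave 17 higher and 4 lower in A (80 and 23), and 12 and 1 in B (46 and 5). With U0126 there were 37 higher and 27 lower in A (70 and 75), and 26 and 17 in B (38 and 37). R5020 + MAA gave 123 higher and 41 lower in A (226 and 55), and 143 and 28 in B (269 and 45). R5020 + U0126 gave 116 and 52 in A (207 and 92), and 96 and 40 in B (154 and 63). The triple treatment gave 168 higher and 56 lower in A (343 and 97), and 188 and 58 in B (343 and 112).

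The series title concerns genes regulated by isoforms of the progesterone receptor, and PGR, the gene of that receptor, fell with R5020 in samples of both letters. Its mean log2 ratio to the pooled control was -1.52 ± 0.10 (SD, n = 8) with R5020, where samples ranged from -1.69 to -1.41. Without R5020 the mean was -0.03 ± 0.24 (SD, n = 4), with a range from -0.30 to 0.22. The fitted change was -1.47 ± 0.08 in A (adjusted p = 7.8e-05) and -1.52 ± 0.08 in B (adjusted p = 7.3e-05). A single probe stood for PGR, so the isoforms cannot be separated.

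**Figure D1:**
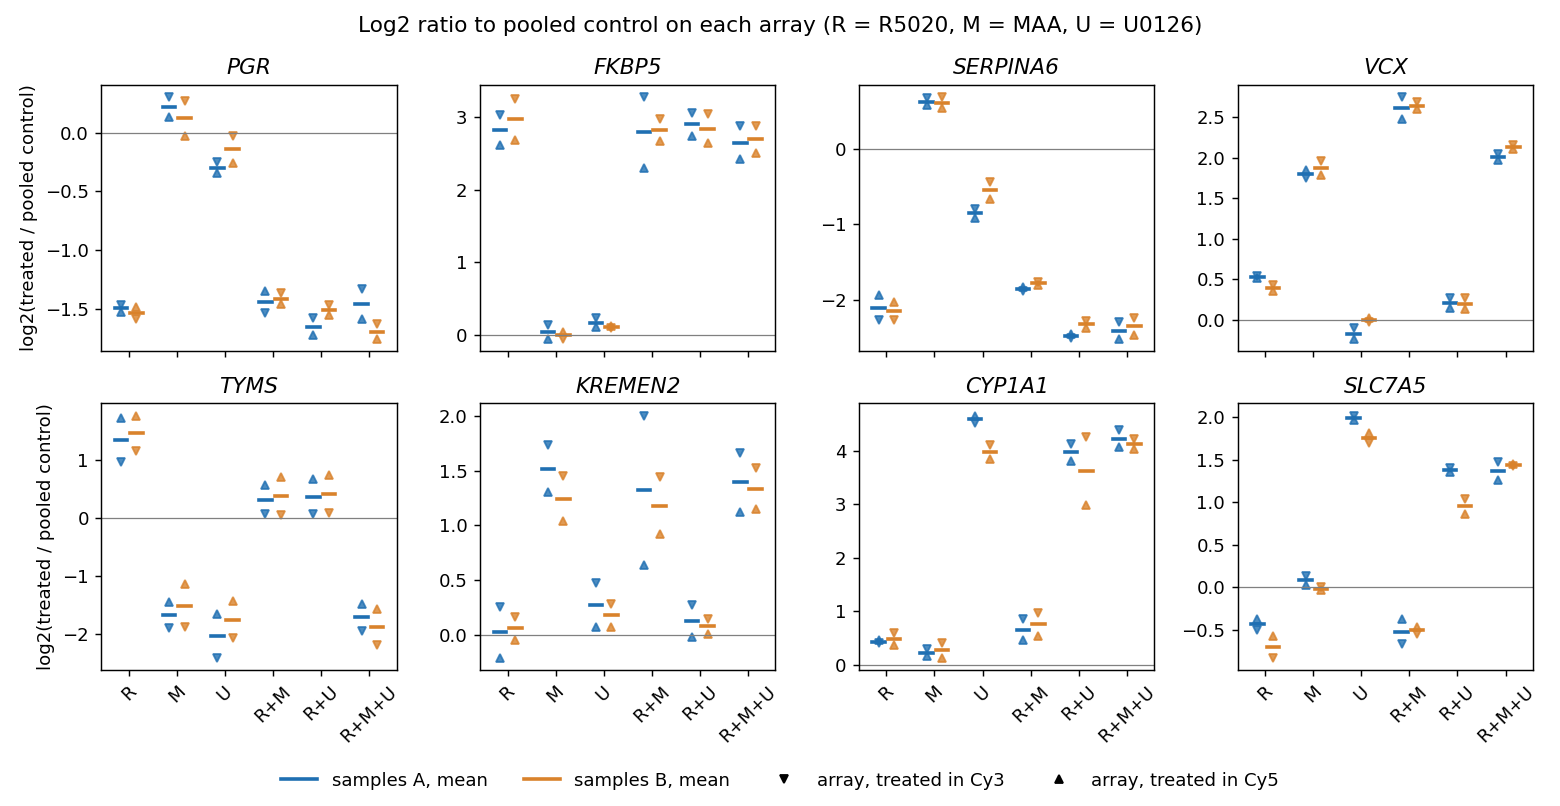
Log2 ratio to the pooled control (vertical axis) of 8 genes by treatment (horizontal axis), with a triangle for each of the 24 arrays and a line for the mean of the 2 arrays of a condition, in samples A (blue) and B (orange). PGR lay between -1.69 and -1.41 in the 8 conditions with R5020, and CYP1A1 had a mean of 4.09 with U0126 and 0.47 without.

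With R5020 in the A samples, most cell cycle genes and progestin targets of the lists rose, while genes including SERPINA6, which encodes corticosteroid-binding globulin, fell. FKBP5, a co-chaperone of steroid receptors and a known progestin target, changed most among the genes named, by 2.69 ± 0.05 (adjusted p = 4.52e-07). Its mean log2 ratio was 2.80 ± 0.11 (SD, n = 4) with R5020 and 0.10 (n = 2) without. ATAD2, a chromatin-binding ATPase, rose by 2.32 ± 0.08 (adjusted p = 1.58e-05). SPC25, a kinetochore protein, rose by 2.02 ± 0.09, and GINS2, a member of the replicative helicase complex, by 1.98 ± 0.14. Others that rose were MRFAP1L2 (2.13 ± 0.16), S100A8 (2.03 ± 0.09), AZGP1 (2.01 ± 0.07), PNMT, the enzyme that makes adrenaline (1.95 ± 0.22), and SOD2, the mitochondrial superoxide dismutase (1.94 ± 0.16). SERPINA6 changed by -2.10 ± 0.18 (adjusted p = 0.000351) and SRARP by -1.77 ± 0.09. ZFP36L2, which promotes mRNA decay, changed by -1.74 ± 0.08, and PREX1 by -1.56 ± 0.10. Also lower were FBP1 of gluconeogenesis (-1.50 ± 0.08), AMIGO2 (-1.30 ± 0.07) and GNG11 (-1.28 ± 0.14).

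Of 34 cell cycle genes measured, 32 rose in A, 0 fell and 2 did not pass, and adjusted over the list alone 34 rose. Their median change was 0.86 (camera adjusted p = 5.84e-30; adjusted p = 0.0904 with an estimated correlation). CDK1, the kinase that starts mitosis, rose by 1.86 ± 0.11, CDC45 of the replicative helicase by 1.20 ± 0.06 and E2F1 by 1.07 ± 0.07. Among 38 progestin targets, 24 rose, 1 fell and 13 did not pass (26 and 1 adjusted over the list alone). Camera gave them an adjusted p of 7.06e-16, and adjusted p = 0.0721 with an estimated correlation, and NET1 rose by 1.51 ± 0.09 and NDRG1 by 1.24 ± 0.05. Of 18 genes of fatty acid synthesis, 7 rose, 1 fell and 10 did not pass (8 and 2 adjusted over the list alone; camera adjusted p = 0.000741). ACSL1 (1 sample without R5020) rose by 1.06 ± 0.08, FASN, the fatty acid synthase, by 0.79 ± 0.06 and FADS1 by 0.78 ± 0.05, and the list's adjusted p = 0.0987 with an estimated correlation. Among 12 metallothioneins, which bind zinc and copper, 4 rose, 0 fell and 8 did not pass (6 and 0 adjusted over the list alone). MT1X rose by 1.43 ± 0.16, MT2A by 1.12 ± 0.08 and MT1E by 1.01 ± 0.15 (camera adjusted p = 0.000102, and adjusted p = 0.252 with an estimated correlation).

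Camera also called 4 further lists in A. Of 19 genes of ER stress and amino acid response, 4 rose, 0 fell and 15 did not pass (5 and 0 adjusted over the list alone), with PHGDH of serine synthesis at 0.82 ± 0.11 (camera adjusted p = 0.00505; adjusted p = 0.663 with an estimated correlation). Of 14 genes that deacetylase inhibitors lower, 7 rose, 2 fell and 5 did not pass (7 and 2 adjusted over the list alone). That list shares RRM2 and TYMS with the cell cycle list (camera adjusted p = 0.035; adjusted p = 0.413 with an estimated correlation). For cholesterol synthesis 3 of 20 rose, 1 fell and 16 did not pass, with a median of 0.11 (3 and 1 adjusted over the list alone; camera adjusted p = 0.035, upward; adjusted p = 0.663 with an estimated correlation). SC5D changed by -0.73 ± 0.09 and CYP51A1 by 0.42 ± 0.09. Among 13 luminal markers 1 rose, 4 fell and 8 did not pass (1 and 5 adjusted over the list alone), with SPDEF at -1.05 ± 0.10, CDH1 at -0.38 ± 0.07 and MUC1 at 0.30 ± 0.04 (camera adjusted p = 0.0415; adjusted p = 0.413 with an estimated correlation). With Feature Extraction's ratios the calls of the cholesterol, deacetylase and luminal lists ended (0.0636, 0.0592 and 0.0896), and that of the cholesterol list also with median centring (0.238) and without background subtraction (0.0563).

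The other 12 lists did not pass camera in A. Steroid receptors had 2 of 14 higher and 3 lower (VDR rose by 0.33 ± 0.08), and adhesion and cytoskeleton had 3 of 29 higher and 8 lower. Estrogen targets had 2 of 22 higher, with GREB1 at 1.31 ± 0.10, and 3 lower. Hypoxia and glycolysis had 4 of 19 higher and 3 lower, and genes raised by deacetylase inhibitors had 5 of 19 higher and 3 lower. For MEK/ERK output 1 of 26 was higher and 2 lower (EPHA4, -1.07 ± 0.06), and for immediate early genes 2 of 23 were higher and 3 lower. Interferon response had 1 of 22 higher and 2 lower, and housekeeping genes had 1 of 15 higher and 2 lower, with a median of 0.03 and a mean of -0.01. Among markers of other cell types, EGFR was the 1 of 11 basal and mesenchymal markers that rose (0.47 ± 0.08), 2 of 9 fibroblast markers fell (LUM, -0.50 ± 0.12), and 0 of 10 leukocyte markers passed. Their adjusted p in camera ran from 0.133 for steroid receptors to 0.906 for leukocyte markers.

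In A, 4298 features passed, 2261 higher and 2037 lower, and 178 were higher and 36 lower by 2-fold or more. A fit of all 24 arrays called 6775, and with extraction day as a block it called 4653, 3302 of them shared with the averages. With the day block the cell cycle median was 0.90, that of progestin targets 0.49, of fatty acid synthesis 0.10 and of metallothioneins 0.17, and those of ER stress, genes lowered by deacetylase inhibitors, cholesterol synthesis and luminal markers were 0.24, 0.18, 0.06 and -0.18. Within a day, R5020 + MAA against MAA gave the same sign for 99.2% of called features, with medians of 1.09 for the cell cycle, 0.46 for progestin targets, 0.21 for fatty acid synthesis and 0.33 for metallothioneins. On another day R5020 + U0126 against U0126 gave 99.2%, with medians of 0.75, 0.33, 0.10 and 0.12, though these arrays had also entered the calls. The count fell to 1768 with median centring, and without U0126 (A), R5020 (A) or R5020 + MAA + U0126 (A) it was 1787, 2659 and 2661. Leaving out the Cy3 array of R5020 + U0126 (B), the Cy5 array of R5020 + U0126 (A) or the Cy3 array of R5020 + MAA (B) gave 2656, 2769 and 2799.

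R5020 in the B samples also raised most cell cycle genes and progestin targets. FKBP5 changed by 2.79 ± 0.05 (adjusted p = 3.44e-07), from a mean log2 ratio of 0.05 (n = 2) without R5020 to 2.84 ± 0.11 (SD, n = 4) with it. MRFAP1L2 rose by 2.15 ± 0.16, ATAD2 by 2.12 ± 0.08, S100A8 by 2.05 ± 0.09 and AZGP1 by 1.98 ± 0.07. PNMT (1.98 ± 0.22), BIRC3, an inhibitor of apoptosis (1.96 ± 0.26, adjusted p = 0.00266), SOD2 (1.89 ± 0.16) and LMNB1, a lamin of the nuclear envelope (1.89 ± 0.19), also rose. SERPINA6 changed by -2.18 ± 0.18 (adjusted p = 0.000338), SRARP by -1.81 ± 0.09 and ZFP36L2 by -1.71 ± 0.08. BTG1, an antiproliferative factor (-1.68 ± 0.13), FBP1 (-1.66 ± 0.13), GNG11 (-1.65 ± 0.21) and SPTSSB (-1.42 ± 0.12) were also lower. BTG1, FBP1 and GNG11 had a value in only 1 of the 2 samples without R5020, U0126 (B), so their changes rest on that sample and on additivity. In the cell cycle list 30 of 34 rose, 0 fell and 4 did not pass (33 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 8.06e-28; adjusted p = 0.0687 with an estimated correlation). CDK1 rose by 1.73 ± 0.11 and CDC45 by 0.89 ± 0.06. For progestin targets 24 of 38 rose, 1 fell and 13 did not pass (26 and 1 adjusted over the list alone), with NET1 at 1.54 ± 0.09 and NDRG1 at 1.16 ± 0.05 (camera adjusted p = 5.04e-19; adjusted p = 0.051 with an estimated correlation).

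Fatty acid synthesis in B had 7 of 18 higher, 1 lower and 10 that did not pass (9 and 1 adjusted over the list alone), with FASN at 0.82 ± 0.06 (camera adjusted p = 9.8e-06; adjusted p = 0.0648 with an estimated correlation). Of 12 metallothioneins 5 rose, 0 fell and 7 did not pass (8 and 0 adjusted over the list alone), with MT2A at 1.54 ± 0.08 (camera adjusted p = 2.69e-05; adjusted p = 0.217 with an estimated correlation). ER stress and amino acid response had 3 of 19 higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.00325; adjusted p = 0.484 with an estimated correlation). Luminal markers had 1 of 13 higher and 4 lower (1 and 6 adjusted over the list alone; camera adjusted p = 0.0231; adjusted p = 0.356 with an estimated correlation). Genes lowered by deacetylase inhibitors had 5 of 14 higher and 3 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.0332; adjusted p = 0.356 with an estimated correlation). The other 13 lists had an adjusted p in camera from 0.0506 for steroid receptors to 0.903 for leukocyte markers.

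In B, 3595 features passed, 2028 higher and 1567 lower, and 160 were higher and 32 lower by 2-fold or more. With median centring 1449 passed, and the balance moved to 1112 higher and 337 lower. The 24 arrays gave 5903, and blocked by extraction day 4064, 3091 of them shared with the averages, with medians of 0.82 for the cell cycle, 0.43 for progestin targets, 0.17 for fatty acid synthesis, 0.30 for metallothioneins, 0.17 for ER stress, 0.14 for genes lowered by deacetylase inhibitors and -0.19 for luminal markers. Within a day R5020 + MAA against MAA gave 99.9% the same sign, with medians of 1.01, 0.55, 0.16 and 0.51, though these arrays had also entered the calls. The count was 1062 without MAA (B), 1154 without U0126 (B), 2046 without R5020 (B) and 2052 without R5020 + MAA + U0126 (B). Without the Cy5 array of R5020 + U0126 (A) it was 2150, and without the Cy3 array of R5020 + U0126 (B) 2344.

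The difference between the letters in the response to R5020 was tested directly, and no gene passed. limma called 0 features, with 942 at an unadjusted p under 0.05. With A and B paired by treatment, a fit chosen after the values were seen, it also called 0 (1071 at an unadjusted p under 0.05). The smallest unadjusted p belonged to KHSRP (0.63 ± 0.12 higher in B, with 1 B sample without R5020), YAP1 (0.53 ± 0.12), APP (0.41 ± 0.09), GBE1 (-0.41 ± 0.08), LGI4 (-0.30 ± 0.07) and TIMM10B (-0.26 ± 0.06), and each had an adjusted p of 0.9998. PGR, FKBP5 and SERPINA6 lay near the line of equal change in the plot of B against A. Of 35648 features tested in both letters, 1697 were higher in both against 129 if the lists were independent, 1203 were lower in both against 89.5, and 0 were called in opposite directions. The letter offset removes the pooled control from each effect, so these overlaps do not come from a shared control. Across genes, which are not independent replicates, the correlation was 0.905 over all tested and 0.970 over the 4993 called in either letter. Among those 4993, 98.9% had the same direction, the median absolute difference was 0.07 and the largest 0.94, and 93.7% had a 95% interval of the difference within 0.5 of 0.

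**Figure D2:**
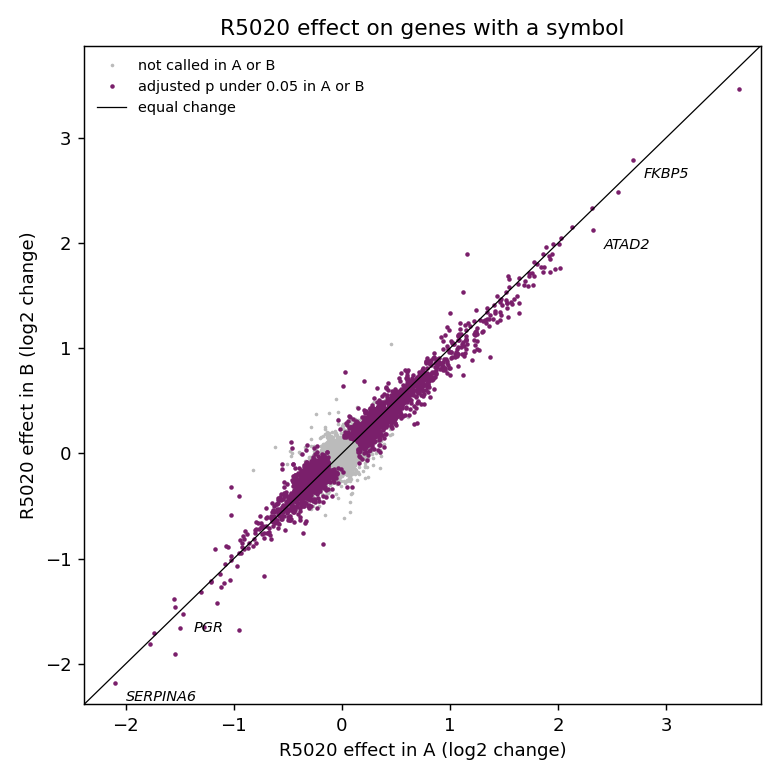
Log2 change with R5020 in B (vertical axis) against A (horizontal axis) for genes with a symbol, where purple points passed in A or B, grey points in neither, and the line marks equal change. Over the 4993 features called in either letter, with and without a symbol, the correlation was 0.970.

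None of the 20 lists had a member that passed the test of this difference. The cell cycle list had a median difference of -0.08 and a camera adjusted p of 0.000485, against adjusted p = 0.967 with an estimated correlation. Its call ended with median centring (0.0986), and its median was -0.14 with extraction day as a block. Leaving out U0126 (A) gave 31 features, all higher in B, and leaving out MAA (B) gave 1. With every probe tested 1 feature passed, and with extraction day as a block 0 did. For MAA no list passed (smallest camera adjusted p 0.52), nor for U0126 (0.163). Paired by treatment, the cell cycle list passed camera downward for R5020 (4.86e-08; adjusted p = 0.772 with an estimated correlation), MAA (0.0229; adjusted p = 0.985 with an estimated correlation) and U0126 (0.000528; adjusted p = 0.933 with an estimated correlation), and limma called 0 features for MAA and U0126. The direct test of the MAA response between letters called 0 features with limma (714 at an unadjusted p under 0.05), with SCARF2 (0.27 ± 0.05), ARHGAP27 (0.37 ± 0.08) and ZNF205 (0.27 ± 0.06) nearest above 0. JAG2, a Notch ligand (-0.37 ± 0.07), ZCRB1 (-0.22 ± 0.05) and RPS15 (-0.21 ± 0.06) were nearest below. The same test for U0126 called 0 features (736 at an unadjusted p under 0.05), and NMNAT2 (0.33 ± 0.05), MELTF (0.31 ± 0.07), SPATA19 (0.27 ± 0.06), MARCHF6 (-0.39 ± 0.08), TAF10 (-0.26 ± 0.06) and KCNAB3 (-0.26 ± 0.06) did not pass. Both counts were 1 without R5020 (A) or without R5020 + MAA + U0126 (A).

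MAA raised genes of the adhesion and interferon lists and lowered cell cycle genes (n = 6 with and 6 without, over both letters). Each of the 6 samples without MAA had R5020, U0126 or both. VCX, a gene of the germ line, rose by 1.89 ± 0.09 (adjusted p = 3.81e-05), from a mean log2 ratio of 0.20 to 2.18 ± 0.37 (SD, n = 6). SLC16A3, which exports lactate, rose by 1.81 ± 0.07 (adjusted p = 1.32e-05), ITM2C by 1.28 ± 0.07, and KREMEN2, a receptor for Dickkopf proteins, by 1.24 ± 0.03 (adjusted p = 2.76e-06). CDKN1C, an inhibitor of cyclin-dependent kinases, rose by 1.14 ± 0.07 and PRAME, a cancer-testis antigen, by 1.18 ± 0.13. Others were SPEG (1.18 ± 0.09), DLX4 (1.16 ± 0.03) and RAB31 (1.11 ± 0.03). TYMS, the thymidylate synthase, changed by -1.54 ± 0.18 (adjusted p = 0.00107), HMGB2 by -1.10 ± 0.10, and ID1, an inhibitor of differentiation, by -1.09 ± 0.06 (adjusted p = 4.52e-05). SCUBE2 (-1.11 ± 0.14), TRIB3 (-1.05 ± 0.18), ALYREF of mRNA export (-1.02 ± 0.04), CDCA5, which holds sister chromatids together (-1.01 ± 0.12), MND1 (-0.96 ± 0.09), SPC25 (-0.94 ± 0.06) and TP53I3 (-0.92 ± 0.06) were lower too.

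Among cell cycle genes 1 of 34 rose with MAA, 28 fell and 5 did not pass (1 and 31 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 8.75e-16; adjusted p = 0.197 with an estimated correlation). CDC45 changed by -0.77 ± 0.04, CCNB2 by -0.67 ± 0.07, CCNA2 by -0.49 ± 0.05 and E2F1 by -0.47 ± 0.05. Genes that deacetylase inhibitors lower had 0 of 14 higher, 8 lower and 6 that did not pass (1 and 9 adjusted over the list alone; camera adjusted p = 0.000418; adjusted p = 0.197 with an estimated correlation), with RRM1 at -0.81 ± 0.07, NCL at -0.37 ± 0.03 and MYBL2 at -0.25 ± 0.03. Genes that such inhibitors raise had 8 of 19 higher, 0 lower and 11 that did not pass (8 and 1 adjusted over the list alone; camera adjusted p = 0.0156; adjusted p = 0.197 with an estimated correlation). GLRX, CLU and SERTAD1 rose by 0.60 ± 0.07, 0.59 ± 0.06 and 0.25 ± 0.03. In adhesion and cytoskeleton 11 of 29 rose, 2 fell and 16 did not pass (15 and 2 adjusted over the list alone; camera adjusted p = 0.000418; adjusted p = 0.197 with an estimated correlation), with LAMB3 at 0.99 ± 0.12, KRT80 at 0.50 ± 0.04, CDH1 at 0.47 ± 0.05 and ITGA3 at 0.35 ± 0.03. Interferon response had 8 of 22 higher, 0 lower and 14 that did not pass (8 and 0 adjusted over the list alone; camera adjusted p = 0.00157; adjusted p = 0.197 with an estimated correlation), with IFITM1 at 0.92 ± 0.08, ISG15 at 0.48 ± 0.03 and BST2 at 0.48 ± 0.03.

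Weaker calls for MAA came from 3 lists, and like those of the lists above, none held with an estimated correlation. Estrogen targets had 4 of 22 higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.0363; adjusted p = 0.335 with an estimated correlation). Immediate early genes had 4 of 23 higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.0458; adjusted p = 0.197 with an estimated correlation). Fibroblast markers had 4 of 9 higher and 0 lower (4 and 0 adjusted over the list alone), with COL1A1 at 0.31 ± 0.03 and ACTA2 at 0.23 ± 0.05 (camera adjusted p = 0.0458; adjusted p = 0.396 with an estimated correlation). All 3 calls ended with Feature Extraction's ratios (0.069, 0.069 and 0.111), that of the fibroblast markers also with median centring (0.0609) and without background subtraction (0.121), and that of the immediate early genes also without it (0.0594). The fit with extraction day as a block gave these 3 lists medians of 0.07, 0.04 and 0.10. Luminal markers moved both ways, with KRT18 at 0.81 ± 0.09, KRT8 at 0.77 ± 0.06 and MUC1 at -0.37 ± 0.03 (4 of 13 higher, 3 lower, median -0.04, mean 0.08, camera adjusted p = 0.82). VIM rose by 0.96 ± 0.06 among basal and mesenchymal markers (2 of 11 higher, 0 lower, median -0.02, mean 0.07, camera adjusted p = 0.945). For progestin targets 4 of 38 rose, including CLDN8 (0.95 ± 0.13), and 3 fell, including NDRG1 (-0.65 ± 0.03), and the camera adjusted p was 0.752. The remaining 9 lists had a camera adjusted p from 0.209 for MEK/ERK output, with 4 of 26 higher and 0 lower, to 0.688 for housekeeping genes, with 2 of 15 higher and 3 lower.

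For MAA 5930 features passed, 2979 higher and 2951 lower, with 23 higher and 9 lower by 2-fold or more. By letter, 2639 passed in A and 3151 in B. With median centring 2516 passed, and the balance moved to 1523 higher and 993 lower. All 24 arrays gave 8198, and with extraction day as a block 8963, 5831 of them shared with the averages, with medians of -0.43 for the cell cycle, -0.23 and 0.15 for genes lowered and raised by deacetylase inhibitors, 0.06 for interferon response and 0.11 for adhesion. Within a day, R5020 + MAA (A) against R5020 (A) gave the same sign for 90.6% of called features, with medians of -0.27 for the cell cycle, -0.14 and 0.01 for genes lowered and raised by deacetylase inhibitors, 0.07 for interferon response and 0.02 for adhesion. The triple treatment against R5020 + U0126 in B on another day gave 99.2%, with medians of -0.47, -0.21, 0.20, 0.06 and 0.12. The arrays of both days had also entered the calls. The count was 2838 without R5020 + MAA + U0126 (B), 3488 without R5020 (A), 3633 without R5020 + MAA + U0126 (A) and 3915 without R5020 (B).

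U0126 raised CYP1A1, CYP1B1 and HMOX1 and lowered cell cycle genes (n = 6 with and 6 without). CYP1A1, a cytochrome P450 that oxidizes aromatic hydrocarbons, rose by 3.65 ± 0.15, or 12.5-fold (adjusted p = 5.63e-05). Its mean log2 ratio was 4.09 ± 0.32 (SD, n = 6) with U0126 and 0.47 ± 0.21 (SD, n = 6) without. HMOX1, the heme oxygenase, rose by 2.23 ± 0.12 (adjusted p = 7.21e-05), CYP1B1 by 2.10 ± 0.11, and SLC7A5, a transporter of large neutral amino acids, by 1.86 ± 0.05 (adjusted p = 7.39e-06). GCLM of glutathione synthesis rose by 1.29 ± 0.12, the thioredoxin reductase TXNRD1 by 1.27 ± 0.09 and the sulfiredoxin SRXN1 by 1.17 ± 0.11. VTCN1 (1.18 ± 0.13), VIPR1 (1.16 ± 0.05) and KLF5 (1.08 ± 0.05) rose too. TYMS changed by -1.67 ± 0.18 (adjusted p = 0.0011) and SPC25 by -1.40 ± 0.06 (adjusted p = 5.63e-05). The histone genes H4C3, H4C2 and H4C13 changed by -1.39 ± 0.14, -1.26 ± 0.10 and -1.21 ± 0.10. Lower as well were ZG16B (-1.38 ± 0.09), LMNB1 (-1.32 ± 0.13), PCLAF (-1.27 ± 0.09), CDCA5 (-1.27 ± 0.12) and MCM3 of the replicative helicase (-1.26 ± 0.12).

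Of 34 cell cycle genes 0 rose with U0126, 32 fell and 2 did not pass (0 and 33 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 6.3e-28; adjusted p = 0.191 with an estimated correlation). CDC45 changed by -0.94 ± 0.04, E2F1 by -0.80 ± 0.05, MCM7 by -0.80 ± 0.07 and CCNA2 by -0.60 ± 0.05. Genes lowered by deacetylase inhibitors, which share RRM2 and TYMS with that list, had 1 of 14 higher, 8 lower and 5 that did not pass (2 and 10 adjusted over the list alone; camera adjusted p = 4.44e-05; adjusted p = 0.191 with an estimated correlation). Luminal markers had 0 of 13 higher and 3 lower (0 and 5 adjusted over the list alone), namely AGR2 (-0.94 ± 0.04), FOXA1 (-0.36 ± 0.09) and MUC1 (-0.12 ± 0.03), with a camera adjusted p of 0.00396 and adjusted p = 0.301 with an estimated correlation. Fatty acid synthesis had 0 of 18 higher and 4 lower (0 and 5 adjusted over the list alone), including FADS1 (-0.45 ± 0.04) and FADS2 (-0.29 ± 0.05), with a camera adjusted p of 0.00842 and adjusted p = 0.191 with an estimated correlation. Metallothioneins had 0 of 12 higher and 2 lower (0 and 4 adjusted over the list alone), MT1E (-0.42 ± 0.11) and MT2A (-0.33 ± 0.07), with a camera adjusted p of 0.0115 and adjusted p = 0.516 with an estimated correlation. That last call ended with Feature Extraction's ratios (0.0505).

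The MEK/ERK output list did not move as a set with U0126 (3 of 26 higher, 4 lower and 19 that did not pass; 3 and 5 adjusted over the list alone; camera adjusted p = 0.584; median -0.02, mean 0.01). DUSP5, a phosphatase of ERK, changed by -0.45 ± 0.03, while IER3 rose by 0.77 ± 0.12, MYC by 0.58 ± 0.06 and EPHA4 by 0.24 ± 0.04. Immediate early genes had 1 of 23 higher and 1 lower (camera adjusted p = 0.989), with EGR1 at -0.13 ± 0.03. ER stress and amino acid response had 6 of 19 higher, among them DDIT3 (0.86 ± 0.13), HSPA5 (0.71 ± 0.12) and SLC7A11, the cystine transporter (0.19 ± 0.03), and 1 lower (camera adjusted p = 0.0676). Hypoxia and glycolysis had 3 of 19 higher and 6 lower (camera adjusted p = 0.0676), and housekeeping genes had 2 of 15 higher and 4 lower, with TFRC at -0.37 ± 0.03 and ACTB at -0.28 ± 0.04 (camera adjusted p = 0.0729). Progestin targets had 5 of 38 higher, including TIPARP (1.003 ± 0.10), and 2 lower (camera adjusted p = 0.506). Cholesterol synthesis had 2 of 20 higher, including FDFT1 (0.62 ± 0.06), and 1 lower (camera adjusted p = 0.411). The remaining 8 lists had a camera adjusted p of at least 0.354. Interferon response and the markers of basal, leukocyte and fibroblast cells had 0 members past the threshold.

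For U0126 4064 features passed, 1902 higher and 2162 lower, with 18 higher and 25 lower by 2-fold or more. By letter, 1487 passed in A and 1813 in B. All 24 arrays gave 6405, and with extraction day as a block 4290, 3190 of them shared with the averages, with medians of -0.64 for the cell cycle, -0.30 for genes lowered by deacetylase inhibitors, -0.11 for luminal markers, -0.09 for fatty acid synthesis and -0.11 for metallothioneins. Within a day, the triple treatment against R5020 + MAA in A gave the same sign for 95.3% of called features, and R5020 + U0126 against R5020 in B on another day gave 94.9%. The arrays of both days had also entered the calls. The cell cycle medians were -0.64 and -0.61, those of genes lowered by deacetylase inhibitors -0.34 and -0.25, those of fatty acid synthesis -0.03 and -0.10, and those of metallothioneins -0.01 and -0.17. Median centring gave 1531 features. Without R5020 + MAA + U0126 (B), R5020 (A), R5020 (B) and R5020 + MAA + U0126 (A) the counts were 1846, 1876, 2188 and 2268, and without the Cy3 array of R5020 + U0126 (B) or the Cy5 array of R5020 + U0126 (A) they were 2573 and 2639.

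R5020 alone against the pooled control (n = 2, with the control's own spread left out) again had FKBP5, PNMT and AZGP1 among its highest genes. S100P, a calcium-binding protein and progestin target, stood at 4.63 ± 0.16, FKBP5 at 2.90 ± 0.04 (adjusted p = 4.89e-11), PNMT at 2.81 ± 0.08, SLPI at 2.53 ± 0.09 and AZGP1 at 2.50 ± 0.05. SERPINA6 stood at -2.12 ± 0.05, the potassium channel KCNC1 at -1.79 ± 0.09, ZFP36L2 at -1.78 ± 0.06 and SRARP at -1.78 ± 0.05. Progestin targets had 28 of 38 higher, 1 lower and 9 that did not pass (29 and 1 adjusted over the list alone), and their call held with an estimated correlation (camera adjusted p = 5.05e-17; adjusted p = 0.0147 with an estimated correlation). Metallothioneins had 8 of 12 higher, 0 lower and 4 that did not pass (9 and 0 adjusted over the list alone), with MT2A at 1.98 ± 0.05 (1 sample) and MT1X at 1.95 ± 0.05, and held as well (5.49e-06; adjusted p = 0.0348 with an estimated correlation). Cell cycle genes had 33 of 34 higher and 0 lower (33 adjusted over the list alone), with UBE2C at 1.75 ± 0.04 and PLK1 at 1.39 ± 0.04 (camera adjusted p = 9.6e-28; adjusted p = 0.0895 with an estimated correlation). Fatty acid synthesis had 8 of 18 higher and 1 lower (camera adjusted p = 0.000374; adjusted p = 0.0522 with an estimated correlation). Cholesterol synthesis had 3 of 20 higher and 11 lower, with a median of -0.12, SC5D at -1.23 ± 0.03 and HMGCS1 at -0.55 ± 0.03 (camera adjusted p = 0.03, downward; adjusted p = 0.208 with an estimated correlation), a call that ended with median centring (0.213). Its direction was opposite to that of the same list for R5020 in A, from the fit over all treatments, and the difference was not tested.

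ER stress and amino acid response had 10 of 19 higher and 1 lower for R5020 alone (camera adjusted p = 0.000914; adjusted p = 0.198 with an estimated correlation), and genes lowered by deacetylase inhibitors had 9 of 14 higher and 3 lower (camera adjusted p = 0.0072; adjusted p = 0.11 with an estimated correlation). Interferon response had 1 of 22 higher and 6 lower (camera adjusted p = 0.0315), and luminal markers had 3 of 13 higher and 8 lower (camera adjusted p = 0.0444), both with adjusted p = 0.256 with an estimated correlation. These last 2 calls ended with Feature Extraction's ratios (0.0502 and 0.0814) and with median centring (0.213 for both). In all 10152 features passed, 5273 higher and 4879 lower, with 225 and 58 by 2-fold or more. All 24 arrays gave 11686, and with extraction day as a block 4358, 4241 of them shared with the averages, with medians of 0.91 for the cell cycle, 0.70 for progestin targets, 0.39 for metallothioneins, 0.17 for fatty acid synthesis, 0.13 for ER stress, 0.17 for genes lowered by deacetylase inhibitors, -0.12 for cholesterol synthesis, -0.05 for interferon response and -0.26 for luminal markers. Median centring gave 5097, and leaving out R5020 (B) gave 6732. The treated RNA and the pool shared each array, and so its day.

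With MAA added to R5020, 257 features passed limma's test of a departure from the sum of both effects, and 4681 had an unadjusted p under 0.05. Small departures could be missed, as recovery in the simulated data was 42% at a log2 change of 0.25. SLPI, an inhibitor of leukocyte proteases, stood below the sum by the most among named genes (-1.18 ± 0.16, adjusted p = 0.0147), followed by P4HA2 (-0.87 ± 0.11, adjusted p = 0.0159), CTSH (-0.82 ± 0.08, adjusted p = 0.00514), SCUBE2 (-0.68 ± 0.07) and GLUL, the glutamine synthetase (-0.68 ± 0.08). CLDN8 stood above the sum by 0.99 ± 0.17 (adjusted p = 0.0337), SERPINA5 by 0.85 ± 0.07 (adjusted p = 0.00374), RCAN1 by 0.84 ± 0.14, PGC by 0.75 ± 0.09 and GINS2 by 0.72 ± 0.13. Many of these calls ended under other settings, in 33 of 48 for GINS2, 29 for CLDN8, 28 for RCAN1, 14 for P4HA2, 13 for SLPI, 10 for GLUL, 4 for SERPINA5 and for SCUBE2 and 3 for CTSH, and in 23 of 46 for PGC. P4HA2 and CTSH had 1 sample with R5020 alone, and PGC had 1 with MAA alone and 1 with both. In cholesterol synthesis 2 of 20 stood above the sum, 0 below and 18 did not pass (7 and 0 adjusted over the list alone), with SC5D at 0.37 ± 0.05 and IDI1, with 1 sample of R5020 alone, at 0.37 ± 0.06 (camera adjusted p = 7e-05; adjusted p = 0.138 with an estimated correlation). Cell cycle genes had 6 of 34 above the sum and 0 below (10 and 3 adjusted over the list alone), with MCM6 at 0.55 ± 0.05 and MCM3 at 0.53 ± 0.05 (camera adjusted p = 0.00299; adjusted p = 0.522 with an estimated correlation). Both calls ended with median centring (0.746 and 0.0989). With extraction day as a block the medians were 0.10 for cholesterol synthesis and 0.07 for the cell cycle.

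Lists below the sum with MAA were estrogen targets, with 0 of 22 past the threshold over all features and 4 lower adjusted over the list alone (camera adjusted p = 0.0049; adjusted p = 0.138 with an estimated correlation), and progestin targets, with 1 of 38 above and 2 below (2 and 5 adjusted over the list alone). MT2A, with 1 sample of R5020 alone, stood at -0.66 ± 0.07 and AREG, an EGFR ligand, at -0.33 ± 0.05 (camera adjusted p = 0.00519; adjusted p = 0.175 with an estimated correlation). ER stress and amino acid response had 0 of 19 above and 1 below, TRIB3 at -0.45 ± 0.08 (0 and 6 adjusted over the list alone; camera adjusted p = 0.00519; adjusted p = 0.291 with an estimated correlation). Metallothioneins had 0 of 12 above and 2 below (0 and 3 adjusted over the list alone), and adhesion had 0 of 29 above and 3 below, including LAMB3 at -0.44 ± 0.07 and ACTN1 at -0.40 ± 0.05 (3 and 7 adjusted over the list alone). Both had a camera adjusted p of 0.0323 and adjusted p = 0.175 with an estimated correlation, and their calls ended in turn with median centring (0.0589; 0.0687 without background subtraction) and with Feature Extraction's ratios (0.103). In total 257 features passed, 125 above the sum and 132 below. Among those with the values needed, the departure in A was opposite to the sum in B for 85.8%, and that in B to the sum in A for 86.6%. Features not called gave 53.5% and 60.8%. Both letters hold the pooled control, which favours opposite signs. The choice of features on the departures of both letters favours them too, and features not called lack that selection. All 24 arrays gave 1022, and with extraction day as a block 117 (42 above and 75 below), 91 of them shared with the averages, with medians of -0.10 for progestin targets, -0.12 for ER stress, -0.10 for estrogen targets, -0.09 for metallothioneins and -0.07 for adhesion, and with median centring limma called 0. No day held, in 1 letter, all the arrays that a departure needs. The count moved by over 1.5 times without 10 of the 12 conditions, to 18 without MAA (A) or R5020 + MAA (A) and 589 without U0126 (B), and without 22 of the 24 arrays.

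Adding U0126 to R5020 departed from the sum for more genes, 1715 in all, 822 above and 893 below, of which 8 and 6 by 2-fold or more. Among those with the values needed, the departure in A was opposite to the sum in B for 89.1%, and that in B to the sum in A for 92.8%. Features not called gave 54.6% and 57.1%. These shares set letters with no treated sample in common beside each other, but both hold the pooled control, which favours opposite signs. The features were also called on the departures of both letters, which favours opposite signs too, and features not called lack that selection. SDC2, a heparan sulfate proteoglycan, stood above the sum by 1.31 ± 0.12 (adjusted p = 0.000762; sum -2.48, combination -1.17), SQLE, the squalene epoxidase, by 1.09 ± 0.14 (adjusted p = 0.00318; sum -1.64, combination -0.55), GINS2 by 1.09 ± 0.13, UHRF1, which maintains DNA methylation, by 1.04 ± 0.08 (adjusted p = 0.000325) and SAT1 by 1.02 ± 0.09. Those below it included CYP1A2 (-1.21 ± 0.20, adjusted p = 0.0117), PNMT (-1.21 ± 0.13, adjusted p = 0.00172), PIR (-1.02 ± 0.08, adjusted p = 0.000318), MT2A (-0.99 ± 0.09) and STC2 (-0.97 ± 0.12). The call of CYP1A2 ended in 9 of 48 settings, and that of each other gene of these 10 in at most 2. SAT1 had 1 sample with R5020 alone, and MT2A had 1 with R5020 alone, in B, and 1 with both, in A. Cholesterol synthesis had 10 of 20 above the sum, 0 below and 10 that did not pass (14 and 0 adjusted over the list alone), with a median of 0.32. HMGCS1, which makes HMG-CoA, stood at 0.86 ± 0.06, SC5D at 0.65 ± 0.05 and DHCR7 at 0.49 ± 0.05, and the call held with an estimated correlation (camera adjusted p = 4.78e-13; adjusted p = 0.0215 with an estimated correlation). Those genes stood below 0 in R5020 alone and in U0126 alone as a list, with medians of -0.12 and -0.27, and the median was -0.09 with both. The list's median was also below 0 with MAA (-0.19), R5020 + MAA (-0.23) and the triple treatment (-0.17). A pooled control higher in these genes than untreated cells could give this, and would place departures above the sum. In the model where the control cancels, the median change was 0.11 with R5020 in A, 0.06 in B and -0.03 with U0126. Whether the control played a part in this call was not tested. ER stress and amino acid response had 8 of 19 above and 0 below (10 and 0 adjusted over the list alone), with HERPUD1 at 0.99 ± 0.15, ATF4 at 0.50 ± 0.06 and DNAJB9 at 0.49 ± 0.07 (camera adjusted p = 1.81e-05; adjusted p = 0.127 with an estimated correlation).

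Metallothioneins had 0 of 12 above and 6 below the sum with U0126 (0 and 7 adjusted over the list alone), with a median of -0.32, MT1X at -0.82 ± 0.08 and MT1E at -0.74 ± 0.09 (camera adjusted p = 8.73e-05; adjusted p = 0.0588 with an estimated correlation). Progestin targets had 2 of 38 above and 5 below (2 and 11 adjusted over the list alone), with S100P at -1.68 ± 0.28, and adhesion had 1 of 29 above and 4 below (1 and 8 adjusted over the list alone). Both had a camera adjusted p of 0.00849, against adjusted p = 0.192 and 0.118 with an estimated correlation, and both calls ended with median centring (0.125 and 0.0799). Cell cycle genes split, with 9 of 34 above and 10 below (12 and 16 adjusted over the list alone), a median of -0.13 and a mean of 0.05 (camera adjusted p = 0.995). MCM6 (0.87 ± 0.05) and MCM3 (0.77 ± 0.05) stood above the sum, while UBE2C (-0.89 ± 0.06) and PLK1 (-0.75 ± 0.06) stood below. MCM4, of the same complex as MCM6 and MCM3 and named after its value was seen, also stood below (-0.41 ± 0.09). CA12 (-0.82 ± 0.06), SLC2A1, the glucose transporter (-0.75 ± 0.08), and CCN1 (-0.56 ± 0.04) were below in the estrogen, hypoxia and immediate early lists. All 24 arrays gave 3548, and blocked by extraction day 461 (252 above and 209 below), 373 of them shared with the averages, and the medians were 0.34 for cholesterol synthesis, 0.23 for ER stress, -0.34 for metallothioneins, -0.05 for progestin targets, -0.12 for adhesion and -0.17 for the cell cycle. Median centring gave 43, and Feature Extraction's ratios gave 691. The count moved by over 1.5 times without 8 of the 12 conditions, to 540 without R5020 (B) and 4164 without U0126 (B), and without 19 of the 24 arrays.

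**Figure D3:**
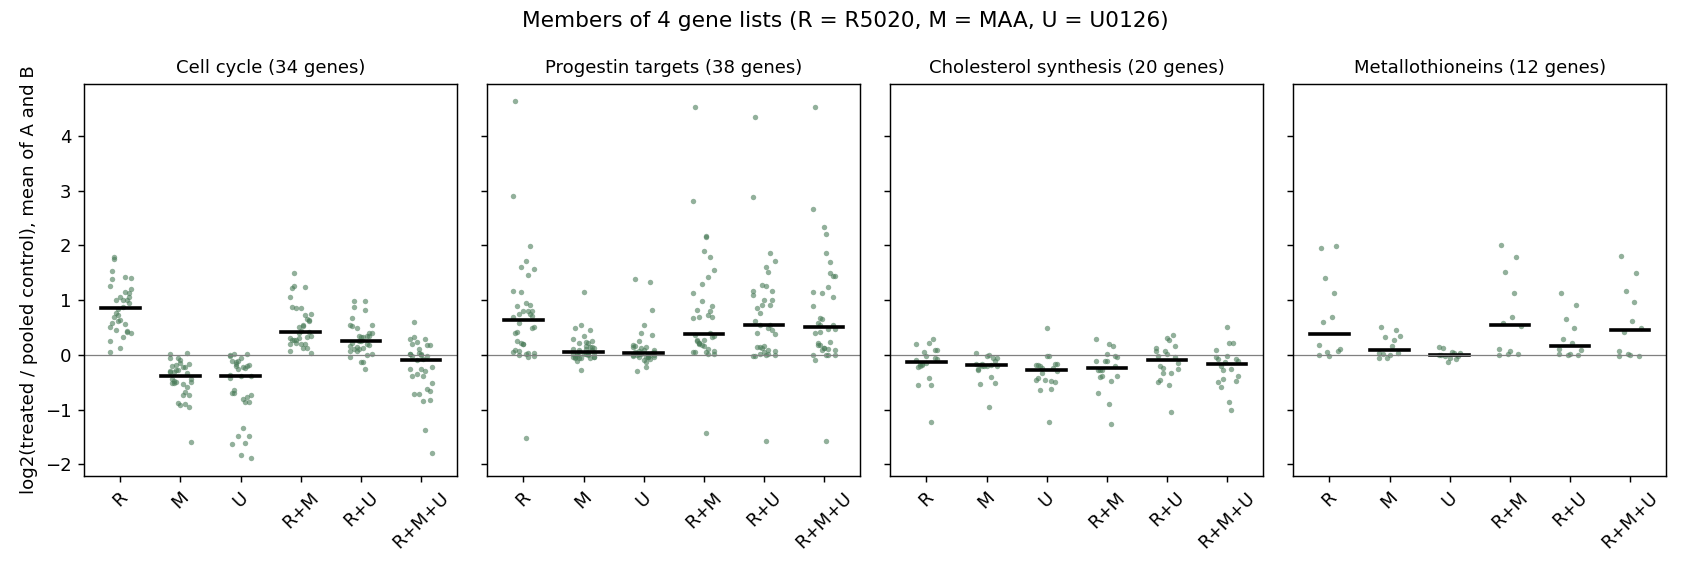
Log2 ratio to the pooled control (vertical axis, mean of A and B) of the members of 4 gene lists by treatment (horizontal axis), with a point for each gene and a bar for the median. The cell cycle median was 0.86 with R5020, -0.39 with MAA and -0.38 with U0126, and the cholesterol synthesis median was -0.12 with R5020, -0.27 with U0126 and -0.09 with both.

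Between the letters over all treatments (6 B against 6 A samples) differences in the ratio to the pooled control were small. The make-up of the pool is not known. A pool that differed between the letters could therefore hide or make a difference here. GGT6 was lower in B by the most among named genes (-0.49 ± 0.06, adjusted p = 0.014), followed by KLC3 (-0.41 ± 0.07), GALNT3 (-0.40 ± 0.08), PDZD7 (-0.40 ± 0.07) and UBOX5 (-0.39 ± 0.07). STMN1, which destabilizes microtubules, was higher in B by 0.37 ± 0.06 (adjusted p = 0.0259), PSMC2 of the proteasome by 0.36 ± 0.06 (adjusted p = 0.0259), RPS3 by 0.29 ± 0.06, FH, the fumarase, by 0.27 ± 0.05 and MMADHC by 0.26 ± 0.05. Most of these calls ended under other settings, out of 47 in 37 for RPS3 and MMADHC, 35 for GALNT3, 34 for FH, 33 for UBOX5, 30 for KLC3 and PDZD7, 28 for PSMC2, 26 for STMN1 and 16 for GGT6. Adhesion and cytoskeleton had 0 of 29 higher in B, 3 lower and 26 that did not pass (1 and 6 adjusted over the list alone), namely MYH9 (-0.23 ± 0.03), DSP (-0.22 ± 0.03) and ACTN1 (-0.16 ± 0.02), with a camera adjusted p of 9.7e-05 and adjusted p = 0.0752 with an estimated correlation. Steroid receptors and their cofactors had 0 of 14 higher and 2 lower (0 and 5 adjusted over the list alone), RXRA (-0.19 ± 0.03) and NCOA1 (-0.12 ± 0.02), with a camera adjusted p of 0.00438 and adjusted p = 0.148 with an estimated correlation. Cell cycle genes had 0 of 34 past the threshold (2 and 0 adjusted over the list alone; camera adjusted p = 0.00608, upward; adjusted p = 0.586 with an estimated correlation). Immediate early genes had 2 of 23 lower, JUN (-0.22 ± 0.04) and CCN1 (-0.11 ± 0.02), with a camera adjusted p of 0.0155 and adjusted p = 0.148 with an estimated correlation, and the luminal marker MUC1 was lower by -0.22 ± 0.02 (list 0.0205; adjusted p = 0.353 with an estimated correlation). Both of these list calls ended with median centring (0.217 and 0.388), and the first also with Feature Extraction's ratios (0.0503).

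In that comparison 616 features passed, 245 higher in B and 371 lower, none by 2-fold. All 24 arrays gave 2288, with the balance turned to 1360 higher and 928 lower, and with extraction day as a block limma called 0, and the medians were -0.05 for adhesion, -0.01 for steroid receptors, 0.01 for the cell cycle, -0.04 for immediate early genes and -0.07 for luminal markers. On the 1 day that held both letters of a treatment in the same dye, R5020 + U0126 (B) against (A) gave the same sign for 87.2% of called features. These arrays had also entered the calls, which favours the same sign. The medians were -0.03 for adhesion and -0.03 for the cell cycle. Feature Extraction's ratios gave 46 (1 higher and 45 lower) and median centring gave 1 (0 higher and 1 lower). The count moved by over 1.5 times whichever of the 12 conditions was left out, from 13 without MAA of either letter to 1337 (754 higher and 583 lower) without R5020 + U0126 of either letter, and without 20 of the 24 arrays, with 0 left without the Cy3 array of R5020 (A).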

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

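The tests of extraction day and of dye bias reported here were chosen only after the results were seen, as was the rule that a median under 2 standard errors leaves a question open. Genes that depart from additivity came up because the departure itself passed its own test. No condition was untreated. A departure therefore holds any interaction of R5020 with the second compound plus any difference between the pooled control and untreated cells. Departures passed for 257 features for R5020 with MAA, among them SLPI and CLDN8, and for 1715 for R5020 with U0126, among them SDC2 and SQLE.

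For R5020 with U0126, a pooled control unlike untreated cells would add the same amount to both departures, so that the slope of the departure with MAA on that with U0126 would be near 1. Over the 1715 features the slope was 0.377 (0.334 in A and 0.420 in B), which argues against the control as the sole cause. A part played by the control stays open, since 139 features passed for both departures, most of them in the same direction, against 12.4 if the lists were independent, and both departures also share the samples with R5020 alone. Extraction day as a block kept 0.995 of the median departure (0.34 before and 0.34 after), which argues against the day as the whole cause. Calls still fell with the day from 3548 in 24 arrays to 461, as the median standard error rose from 0.07 to 0.11. Median centring kept 1.03 of the median departure (0.35). Its calls fell from 1715 in the averages to 43, as the median standard error rose from 0.06 to 0.11. Centring removes no intensity-dependent dye bias, so it cannot test for that bias. An interaction between the progestin and U0126 in the cells is a candidate explanation, not separated from a part played by the control. The departures were found and tested on the same data, and whether the cultures were separate is not known.

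The difference between B and A over all treatments had 589 calls on the 31480 features measured in all conditions. None of the other 31 of 32 splits that exchange the letters within treatments called any (1 of 32 splits as large, highest other 0). Those splits hold any difference between the letters in their residual, and 1 of 32 is the smallest share possible. Chance differences between the samples are therefore not excluded. A dye effect common to all arrays cancels, as every condition averages both orientations. Median centring kept 1.04 of the median size (0.17 before and 0.18 after, standard error 0.03 and 0.05). Its calls over all features fell from 616 to 1. Centring removes no intensity-dependent dye bias, so it cannot test for that bias. Extraction day as a block kept 0.831 of the median size (0.14), with a standard error that rose from 0.03 to 0.07 and 0 calls. A part played by the day stays open, since some days held arrays of 1 letter only. Biological differences between the A and B samples remain possible and untested, since the labels do not say how they differ. A pooled control that differed between the letters was not tested either, since its make-up is not known.

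For MAA, 1 of 100 splits of the samples within letters, the real one, called as many genes (5440, highest other 2), and for U0126 also 1 of 100 (3745, highest other 421). The other splits hold the effect of the compound in their residual, so they call few genes by construction. Whether the cultures were separate is not known, so the splits do not exclude chance differences between the samples.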

How the results depend on the processing

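All alternatives were planned except the pairing of A and B by treatment, which left the 3 differences between letters in a response at 0. None turned the direction of a named gene that had passed. Among all called features, extraction day as a block kept the sign of 98.0% for R5020 alone and of at least 99.8% in each other comparison with calls. No background subtraction, no filter and the strict filter left every count within 1.5 times, while Aquantile does not change log ratios and so tests nothing here. Whether signal over background limits small changes was not tested, and slide print batch was not run because the files do not give it. The cause of the shifts below was not tested, except that a threshold of 0.01 is stricter by construction. Feature Extraction's ratios, and the deposited table that equals them, gave 39 for the departure with MAA, 691 for that with U0126 and 46 for B minus A over all treatments. Median centring gave 1768 and 1449 for R5020 in A and B, 2516 for MAA, 1531 for U0126, 5097 for R5020 alone, 0 and 43 for the departures with MAA and U0126, and 1 for B minus A. Every probe gave 1 for the R5020 difference between letters. No letter term gave 64 and 700 for the departures. A threshold of 0.01 gave 1980, 1574, 3161, 1883, 32, 385 and 31 for R5020 in A and B, MAA, U0126, both departures and B minus A. All 24 arrays with a dye term gave 6775, 5903, 8198, 6405, 11686, 1022, 3548 and 2288 for R5020 in A and B, MAA, U0126, R5020 alone, both departures and B minus A. Extraction day was added as a block to that 24-array fit and gave 4653, 4064, 8963, 4290, 4358, 117, 461 and 0 in that order.

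Leaving out a condition or an array in turn gave 1787 to 4971 for R5020 in A, 1062 to 4649 in B and 0 to 31 for their difference. The ranges were 2838 to 6167 for MAA, 1846 to 4464 for U0126 and 0 to 1 for either difference between letters. They were 6732 to 11350 for R5020 alone, 18 to 589 and 540 to 4164 for the departures, and 0 to 1337 for B minus A. Values that reversed were of genes that had not passed. MELTF (U0126, B minus A) ranged from -0.10 without R5020 + MAA + U0126 (A) to 0.53 without the Cy5 array of R5020 + MAA (A), and YAP1 (R5020, B minus A) from -0.0053 without the Cy3 array of MAA (A) to 1.07 without its Cy5 array. The named genes made 138 entries over all comparisons, of which 120 had passed, and 20 lost the threshold with Feature Extraction's ratios, 23 with median centring, 2 without background subtraction, 6 without a letter term, 17 at 0.01, 1 with a dye term and 14 with extraction day. With a condition or array left out, 4577 of their values kept their side of the threshold, 383 lost it and 1 gained it. List calls lost were 11 of 55 with Feature Extraction's ratios, 13 with median centring and 4 without background subtraction.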

Other observations

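Each test of this part had its prediction set before the members it measures were looked at, though both hypotheses came from genes already seen. The triple treatment belonged to no comparison of its own. Its cell cycle median against the pooled control was -0.09, where R5020 alone stood at 0.86, R5020 + MAA at 0.42 and R5020 + U0126 at 0.25. Progestin targets kept a median of 0.51 in the triple treatment, beside 0.63 with R5020, 0.38 with R5020 + MAA and 0.55 with R5020 + U0126. Metallothioneins stood at 0.46, beside 0.38, 0.55 and 0.17 in those treatments, and cholesterol synthesis at -0.17, beside -0.12, -0.23 and -0.09. These medians are over genes, were not tested against each other and share the pooled control. MAA alone against the pooled control called 7657 features and U0126 alone 6992.

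The rise of HMOX1, GCLM, TXNRD1 and SRXN1 with U0126 may reflect activity of NRF2, the transcription factor of the antioxidant response. The other 20 targets measured had a median change of 0.28, with 12 higher and 0 lower (13 and 0 adjusted over the list alone), and a camera p of 1.12e-10, or p = 0.05 with an estimated correlation. FTL rose by 1.05, TKT by 1.04, NQO1 by 0.93, PRDX1 by 0.74 and SQSTM1 by 0.73. PIR and SLC7A11 had been seen before and were left out. The test could have come out the other way, but RNA levels do not measure NRF2 itself, and other regulators of these genes were not tested.

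CYP1A1 and CYP1B1 are targets of the aryl hydrocarbon receptor, whose activity with U0126 is a possible explanation for their rise. The other 8 targets measured had a median change of -0.00035, with 1 higher (NQO1, which is also in the NRF2 list), and a camera p of 0.315. The prediction of a rise as a set was not met. The question stays open, because the test left out targets already seen that had changed, among them TIPARP (1.003), while CYP1A2 (0.90) had an adjusted p of 0.0627 in limma. That a list without such genes excludes nothing was decided after the value was seen.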
